A study of Homo sapiens with 6 samples.

How the data were processed

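Total RNA from the ovarian clear cell carcinoma line OVSAYO was measured on 6 single-colour Illumina expression arrays, 1 per sample, after biotin labelling. Per the labels, 3 cultures received a negative control hairpin inhibitor and 3 received a mixture of hairpin inhibitors of miR-30a and miR-30d, and RNA was taken 48 hours after transfection. The labels call the 3 samples of each group biological replicates and do not say what separated them, so p-values measure the spread between these samples. The series' design text speaks of mimics where the sample labels and the treatment protocol speak of inhibitors, and the sample labels were followed.

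The deposited values of each array were the mean bead signal of each of 48803 probes, an intensity on a linear scale that the values show to be neither background-subtracted nor normalized between arrays, and a detection score, which rose with the signal from 0 to 1 and was read as 1 minus the detection p. Per the submitters' processing notes, BeadStudio made these tables, and its version is not given in the sources used here. A second deposited table of the whole series held an intensity per probe and array. Each of its columns was an increasing function of that array's own signal, had a median of 48.2 and, for control replicate 1, equalled the signal at all 48803 probes. Its values are thus on a linear scale and were mapped by the authors onto the distribution of control replicate 1, by a method not given in the sources used here.

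The array tables and the series table carried different probe identifiers. They were joined by the rank of each probe on all 6 arrays, which was unique for all 48803 probes. When the join was made on 5 arrays, the rank on the left-out array was right for all 48803 probes in every case. Gene symbols came from the platform annotation that was supplied with the data. In it 28098 probes had 1 symbol, 13 had several and 20692 had none here, and probes with several or none were not named. Of the named probes, 28059 matched an Entrez identifier in the RefSeq table of GRCh38.p14 and 0 symbols needed updating. The files name no genome build, so no coordinates are given.

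Signals were background-corrected and quantile-normalized on the log2 scale with limma's neqc (limma 3.58.1 in R 4.3.3), which inferred the negative controls from the detection values and used an offset of 16. Probes with a detection score above 0.95 on at least 3 of the 6 arrays were kept, which left 21928. For gene-level values the kept probe with the highest mean over all arrays stood for each gene, which gave 12183 genes, and probes of 1 gene that differed in direction are named in the text. Differences were tested with limma's lmFit and eBayes, two-sided, without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 26 lists, and the median of a list was also ranked among 10000 random lists of the same size matched on mean level. A list score is the mean over its genes of the log2 value minus the control mean.

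The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. That rule picks the 10 genes with the lowest p in each direction where none passed the threshold, up to 4 genes with the lowest p of each list, up to 8 of the reported miR-30 targets, and the host genes of miR-30a and of miR-30e and miR-30c-1. Not all the picked genes are named in the text. Alternatives covered background correction, normalization, the series table, detection filters, the offset, the estimate of spread, array weights, the replicate number as a block, each array left out, other set tests and the mean of a gene's probes. A planned test of miR-30 seed sites was not run because no 3′ UTR sequences were at hand, and the chip was not used as a block because the files identify none. Single-colour arrays have no read depth, and the number of arrays limits the precision.

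The procedure was tested on simulated data with the means and spread of these arrays and independent noise, in which 200 of the 21928 probes were changed. At a 1.25-fold change 14% of the changed probes passed the threshold, at 1.5-fold 98%, and at 2-fold and 4-fold 100%. Figures were drawn with matplotlib 3.10.9.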

Results

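The data describe the mRNA response of OVSAYO cells, a line from an ovarian clear cell carcinoma, to inhibitors of miR-30a and miR-30d, members of the miR-30 family. Members of this microRNA family share a seed sequence and lower the abundance or translation of mRNAs that pair with it. Per the labels, miR-30a was more abundant in clear cell cultures than in the cultures they call NOSE, and the comparison asks what its inhibition changes. In the inhibitor group 44 nM of a miR-30a inhibitor and 22 nM of a miR-30d inhibitor were transfected together, and the control group received 66 nM of an inhibitor with minimal similarity to human microRNAs. There were 3 arrays per group. The mean raw signal ran from 222.6 to 258.5, and between 43.4% and 45.2% of the probes were detected on each array.

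With the miR-30a and miR-30d inhibitors, expression shifts were small, and no single gene passed the threshold. How far the inhibitors lowered miR-30 activity was not measured on these arrays. The highest log2 fold change was 0.56 and the lowest was −0.57, with a median standard error of 0.08 over 12183 genes. The genes of the integrated stress response, which cells use to adapt to amino acid shortage and protein-folding stress, were higher as a list, with an adjusted p of 1.76e-05 with camera at the preset correlation, 0.757 with an estimated correlation and 0.179 with fry. Reported miR-30 targets were on balance slightly higher, a difference that did not pass the threshold over the lists.

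Of the 21928 probes tested, 0 passed an adjusted p of 0.05 with limma, and the lowest adjusted p was 0.440. At an unadjusted p under 0.05 there were 2199 probes, or 10.0% against 5% by chance, of which 1060 were higher and 1139 lower with the inhibitor. A Welch test on the same values also gave 0 probes after adjustment and 1408 before it. At the gene level the lowest adjusted p was 0.384, and 1318 genes had an unadjusted p under 0.05. In 1988 genes, 16.3% of those tested, the values of the 2 groups did not overlap, where chance gives 10%. These shares by chance hold for a single probe or gene and do not give the spread of the counts. The 9 other splits of the arrays into groups of 3 gave 416 to 3085 probes, and 2 of them gave as many as the labelled one. With median centring in place of quantile normalization, 4099 probes at the unadjusted threshold were higher and 248 lower. The count of probes at the unadjusted threshold depended on single arrays, from 1304 without inhibitor replicate 1 and 1427 without inhibitor replicate 2 to 4259 without inhibitor replicate 3.

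Among the genes with the lowest p in the direction of higher expression, ZBTB26 (ILMN_1718668), a zinc finger gene, had a log2 fold change of 0.43 ± 0.07 (SE), from 5.28 ± 0.07 (SD) in the controls to 5.71 ± 0.05 in the inhibitor group. IP6K2 (ILMN_1683328), an inositol hexakisphosphate kinase, had 0.38 ± 0.07, while its other kept probe had 0.12. CLDN16 (ILMN_1707670), a tight junction protein of the kidney tubule, had 0.39 ± 0.08 at a high mean level of 11.02 in the controls. The other kept probe of CLDN16, at a lower signal, had 0.17. The glucuronosyltransferase genes UGT2B10 and UGT2B28 had 0.42 and 0.37. They are close paralogs, and whether their probes tell them apart was not checked. PRDM1 (ILMN_1655077), a transcriptional repressor and a reported miR-30 target, had 0.40 ± 0.07, while its other kept probe, at a lower signal, had −0.11. SHLD1, C19orf73, FAM163A and NUDT18 had 0.40, 0.44, 0.46 and 0.32. SHLD1 was detected on 1 of 3 control arrays. All 10 had a limma adjusted p of 0.384, and in each the 3 inhibitor values lay above the 3 control values.

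**Figure D1:**
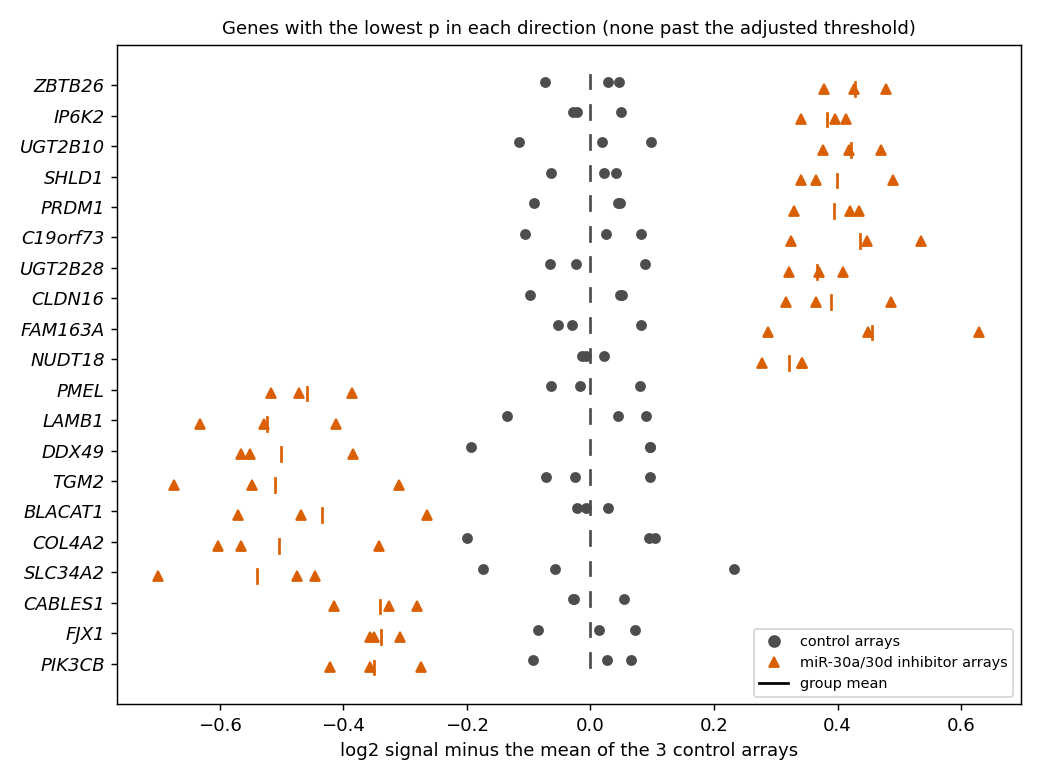
Log2 signal of each array minus the mean of the 3 control arrays (x axis) for the 10 genes with the lowest p in each direction (y axis). Circles are control arrays, triangles are inhibitor arrays and vertical marks are group means. The groups do not overlap in any of these genes, which were picked by their p, and the means differ by 0.32 to 0.46 in the higher genes and by −0.34 to −0.54 in the lower ones.

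Among the genes with the lowest p in the direction of lower expression, LAMB1 (ILMN_1658709), a laminin chain of basement membranes, had a log2 fold change of −0.52 ± 0.09 (SE), from 10.01 ± 0.12 (SD) in the controls to 9.48 ± 0.11 in the inhibitor group, while its other kept probe had 0.13. COL4A2, a collagen IV chain, had −0.50 ± 0.10. TGM2 (ILMN_1705750), a transglutaminase that crosslinks matrix proteins, had −0.51 ± 0.10, and its further probes had −0.35 and 0.02. SLC34A2, a phosphate transporter, had −0.54 ± 0.11, while its other kept probe, at a lower signal, had −0.12. PMEL, a melanosome protein, had −0.46 ± 0.07. PIK3CB, a catalytic subunit of PI3 kinase, had −0.35 ± 0.08. DDX49, BLACAT1, CABLES1 and FJX1 had −0.50, −0.43, −0.34 and −0.34. All 10 had a limma adjusted p of 0.384.

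Of 56 genes reported in the literature as miR-30 targets, 44 were measured, and 29 were higher and 15 lower with the inhibitor, with a median log2 fold change of 0.04. The list's adjusted p was 0.328 with camera (unadjusted p 0.0252), 0.757 with an estimated correlation and 0.179 with fry. Its median lay at percentile 95.1 of random lists. No member passed over all genes, and adjusted over the list alone 2 rose, PRDM1 and AVEN. AVEN, an inhibitor of apoptosis, had 0.51 ± 0.11 (SE) and was detected on 1 of 3 control arrays. The cofilin gene CFL2 had 0.26, the cytokine signalling suppressor SOCS1 had 0.29, the glycosyltransferase GALNT1 had 0.27, SMAD1 had 0.25 and the vesicle coat gene SEC23A had 0.17. The calcineurin subunit PPP3CA went the other way at −0.30. The list score was higher on all 3 inhibitor arrays, at 0.08, 0.05 and 0.05, than on the controls, at 0.01, −0.01 and 0.00. Such a separation also occurred in other lists that did not pass. Replication histone scores were higher on every inhibitor array, and those of hypoxia and glycolysis, ribosomal protein and endothelial genes were lower. The mature microRNAs were not measured on these arrays. The miR-30a host gene LINC00472 had 0.10 ± 0.08 (limma adjusted p 0.663) and NFYC, host of miR-30e and miR-30c-1, had 0.05 ± 0.07 (adjusted p 0.822), and neither reports on an inhibitor that acts on the mature microRNA.

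The integrated stress response list rose with the inhibitor, with 18 of its 20 genes higher, a median log2 fold change of 0.15 and an adjusted p of 1.76e-05 with camera. The call was lost with an estimated correlation of 0.15, at a camera adjusted p of 0.757 with that estimate (unadjusted p 0.0498). It was also lost with fry, at an adjusted p of 0.179 (unadjusted p 0.0138). The fry test for change in either direction gave an adjusted p of 0.0324. Adjusted over the list alone 4 genes rose, and over all genes 0 did. These were STC2, a secreted glycoprotein, with 0.37 ± 0.08 (SE), ASNS, which makes asparagine, with 0.26 ± 0.08, the stress sensor SESN2 with 0.27 ± 0.08, and PHGDH, the first enzyme of serine synthesis, with 0.27 ± 0.08. The other kept probe of ASNS had −0.16. The mean list score was 0.14 ± 0.02 (SD) on the inhibitor arrays, which all lay above the controls at 0.00 ± 0.05. Further members were named after their values were seen. The transcription factor gene ATF4 had 0.16, the serine pathway gene PSPH 0.18 and the cystine transporter SLC7A11 0.20, none of which passed adjusted over the list alone. VLDLR and TRIB3 were the members with negative values, −0.08 and −0.07. SESN2 is also in the list of p53-induced genes, and 3 members in all are in another list.

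**Figure D2:**
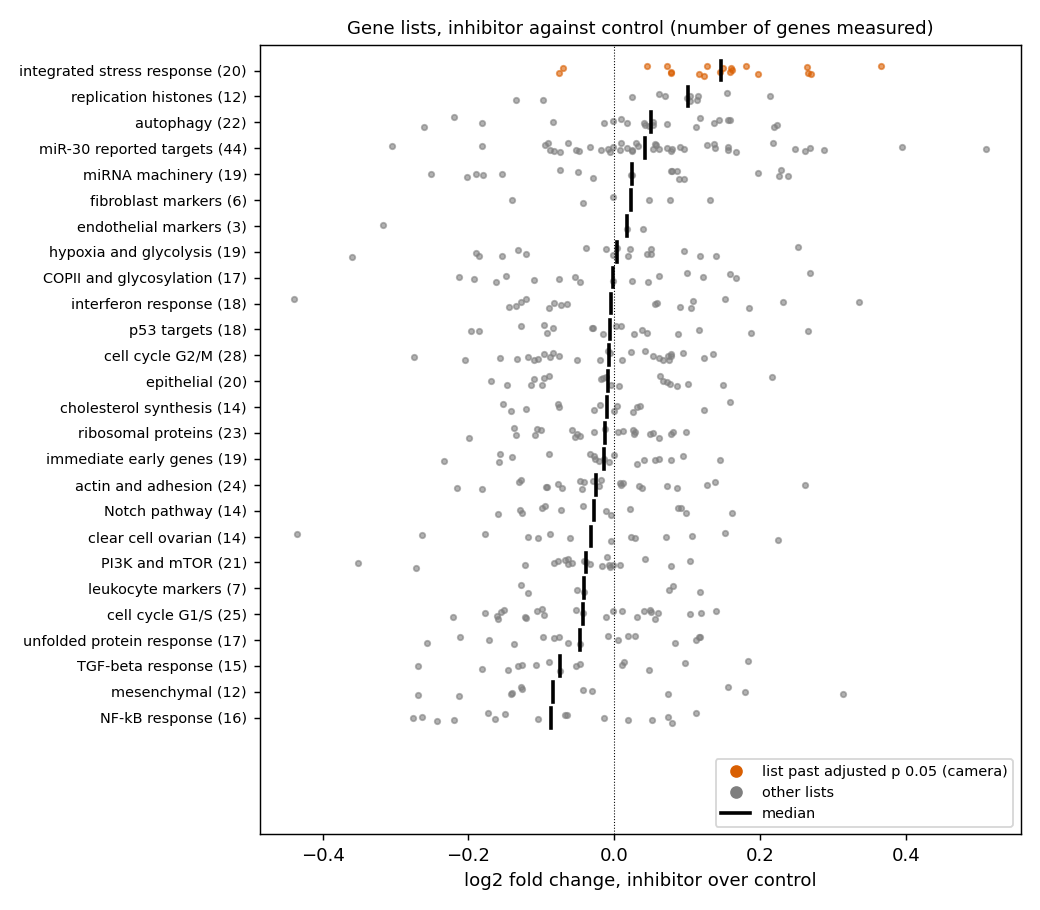
Log2 fold change, inhibitor over control (x axis), of the measured genes of each of 26 lists (y axis), with the number of genes in parentheses. Points are genes and vertical bars are medians. The integrated stress response list, with a median of 0.15, has an adjusted p under 0.05 with camera at the preset correlation, against 0.757 with an estimated correlation and 0.179 with fry.

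The other 25 lists did not pass the threshold, with camera adjusted p from 0.328 to 0.949. Of the stress lists, the unfolded protein response had 7 genes higher and 10 lower, with EDEM1 at −0.26 and CALR at −0.21, and autophagy had 16 higher and 6 lower, with WIPI1 at 0.22, ATG12 at 0.22 and ATG16L1 at −0.26. The p53-induced genes had 9 higher and 9 lower. Hypoxia and glycolysis had 10 higher and 9 lower, with HK2 at −0.36 and ANKRD37 at 0.25, and its median and test differed in sign. Cholesterol synthesis had 7 higher and 7 lower.

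Among signalling lists, PI3K and mTOR had 4 genes higher and 17 lower, with a median of −0.04 and an adjusted p of 0.332 with camera. The fry test for change in either direction gave an adjusted p of 0.0324. Adjusted over the list alone 1 of them fell, PIK3CB. INSR had −0.27 but was detected on only 2 of 3 control and 1 of 3 inhibitor arrays. The NF-kB response had 5 higher and 11 lower, with a median of −0.09 and an adjusted p of 0.332, and CCL20 had −0.28 and TNFAIP3 −0.24. This list passed the threshold as lower without control replicate 1 (camera adjusted p 0.0313) and without inhibitor replicate 3 (camera adjusted p 0.00269). With an estimated correlation the adjusted p of those fits was 0.914 and 0.812. TGF-beta response genes had 5 higher and 10 lower, Notch pathway genes 5 and 9, and immediate early genes 8 and 11. Interferon response genes had 9 higher and 9 lower, with ISG15 at −0.44 and IFIT3 at 0.34, and a median and mean that differed in sign. The other kept probe of IFIT3, at a lower signal, had 0.04.

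Of the lists on cell identity and growth, G1/S genes had 10 higher and 15 lower and mitotic genes 13 higher and 15 lower, with TPX2 at −0.27. Both passed the threshold as lower without inhibitor replicate 3, with camera adjusted p of 0.0363 and 0.0388. With an estimated correlation the adjusted p of that fit was 0.812 for G1/S and 0.814 for mitotic genes. Neither list passed without both control replicate 2 and inhibitor replicate 3, the arrays with the highest mitotic scores. Epithelial genes had 9 higher and 11 lower, mesenchymal genes 4 and 8, and genes of clear cell ovarian carcinoma 6 and 8, with GLRX at −0.44. Actin and adhesion genes had 10 higher and 14 lower, COPII and glycosylation genes 8 and 9, ribosomal protein genes 11 and 12, microRNA machinery genes 11 and 8, and replication histone genes 10 and 2 with H2AC6 at 0.21. Markers of other cell types were sparse, with 6 fibroblast, 7 leukocyte and 3 endothelial markers measured. Adjusted over the list alone the endothelial marker PECAM1 fell, at −0.32, and that list's median and mean differed in sign.

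Arrays also differed within the groups. The first principal component held 42.1% of the variance. Control replicates 1, 2 and 3 lay at −4.12, −15.7 and −1.67, inhibitor replicate 3 lay on their side at −9.11, and inhibitor replicates 1 and 2 lay at 17.5 and 13.2. The mitotic list score was 0.11 on inhibitor replicate 3 against −0.08 and −0.10 on the other inhibitor arrays, and 0.05 on control replicate 2 against −0.03 and −0.01. NF-kB scores split the same way, at 0.15 on inhibitor replicate 3 and 0.12 on control replicate 2.

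**Figure D3:**
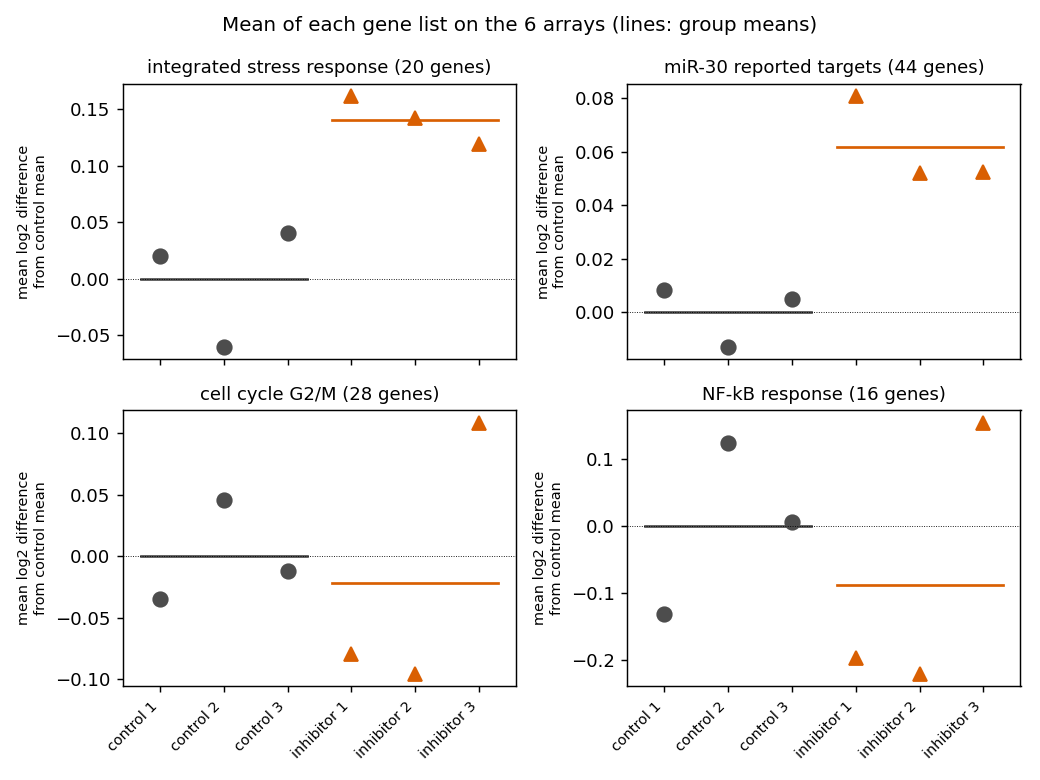
Mean log2 difference from the control mean (y axis) of 4 gene lists on each of the 6 arrays (x axis). Circles are control arrays, triangles are inhibitor arrays and lines are group means. The integrated stress response and miR-30 target scores are higher on every inhibitor array than on any control array, while the mitotic and NF-kB scores are highest on inhibitor replicate 3 and control replicate 2. Some lists not drawn here, which did not pass the threshold, also separate the groups.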

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

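The fit without control replicate 2 and inhibitor replicate 3, and the estimated correlation with 1 array left out, were chosen after the data were seen, and the others before. Probes and genes past the threshold stayed at 0 with limma under every alternative run, against 2199 probes at an unadjusted p under 0.05 and 1408 with Welch's test. The fixed lists past the threshold numbered 1, and between 1 and 4 with 1 array left out, or 0 in each of those fits with an estimated correlation. They were 2 without control replicate 2 and inhibitor replicate 3, where the NF-kB response was lower (camera adjusted p 0.0232). That fit has no value with an estimated correlation here. Over all 6 arrays the lists past the threshold were 0 with an estimated correlation or with fry. Of 9 other splits of the arrays, counted after the data were seen, 5 gave more lists than the labelled one. The integrated stress response kept its direction throughout. Its adjusted p was 0.757 with an estimated correlation and 0.179 with fry, from 1.80e-05 to 0.00176 with 1 array left out, and 0.0178 without control replicate 2 and inhibitor replicate 3. The reported miR-30 targets did not pass under any alternative, with an adjusted p from 0.0964 to 0.757. Median centring moved the median of all genes to 0.12, and the count of unadjusted calls then split into 4099 higher and 248 lower. Relative to the median of all genes, the integrated stress response median lay between 0.11 and 0.18 and that of miR-30 targets between 0.02 and 0.07 over 17 alternatives. Of the 120 genes picked by the naming rule, 0 passed under any alternative, and 13 changed sign under at least 1, of which 9 did so under median centring alone, with its shift of all genes. Replicate numbers did not pair the samples: deviations of the same number correlated at 0.0890, −0.258 and −0.213 across probes. With the replicate block 0 probes passed and the integrated stress response had an adjusted p of 3.41e-05, while the miR-30 seed sites and the chip as a block were not run. Signal over background limits the measurement, with 21928 of 48803 probes kept. The causes of these differences were not tested.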

Other observations

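Of the tests in this part, the counts of splits for probes and for lists past the threshold and the exchange of control replicate 3 with inhibitor replicate 3 were chosen after their results were seen, and the basement membrane list was written after LAMB1 and COL4A2 had been seen. The bound used for array brightness was also tightened after its value was known, to a margin of 1 SD over the pairs of arrays.

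Control replicate 2 and inhibitor replicate 3 stood apart from their groups in single genes, which were picked after their values were seen. Relative to its group mean, the folate receptor gene FOLR1 was −0.34 on control replicate 2 and −0.72 on inhibitor replicate 3, and the defensin DEFB1 was −0.48 and −0.61. The cytokine gene CXCL8 was 0.36 and 0.70 on the same arrays, IL6 was 0.31 and 0.58, and ID3 was 0.35 and 0.52. Relative to the group mean of each array, list scores were −0.06 and −0.07 for epithelial genes. They were −0.08 and −0.10 for mesenchymal genes, and −0.03 and −0.12 for clear cell genes.

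The integrated stress response genes were higher with the inhibitor. A bias that depends on signal level is argued against by the list's percentile of 100 among matched random lists. A single array is argued against by the lowest median with 1 array left out, which was 0.752 of the median over all arrays. For the unlabelled difference between arrays, the gap between the lowest inhibitor and the highest control score was 0.0788. The list was singled out because it differed between these same groups, so the gap cannot decide. Control replicate 2 and inhibitor replicate 3 had the lowest scores of their groups (−0.06 and 0.12), and whether that difference contributes stays open. Higher ATF4 activity predicted that a second list of ATF4 targets would also be higher. Of its 28 measured genes 14 were higher and 14 lower, with a median log2 fold change of −0.00013 (camera p 0.756). Its score was 0.01 ± 0.01 (SD) on the inhibitor arrays, with an SD of 0.02 on the controls. For the genes covered, that argues against a shift shared by ATF4 targets in general. It does not settle what raised the first list. Among 10 splits of the 6 arrays the real one alone (1) reached its camera p of 6.78e-07. The other splits gave this list camera p of 0.000877, 0.00193, 0.00445, 0.00849, 0.0205, 0.0219, 0.488, 0.750 and 0.790. At the preset correlation a camera p under 0.05 for this list was thus not particular to the labelled split. In 7 splits, the real one included, as many lists passed the threshold as its 1, up to 6. These 10 splits are too few for a share under 0.05. A response to the treatment may underlie the shift, as a hypothesis, and the loss of the call with an estimated correlation (adjusted p 0.757) leaves it uncertain.

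Control replicate 2 and inhibitor replicate 3 lay together, and the number of probes was not specific to the labelled split. Exchanging the labels of these arrays gave 807 probes at an unadjusted p under 0.05 against 2199. After the exchange 2 fixed lists passed the threshold, against 1 before. The count of probes cannot decide on exchanged labels, since splits that mix the groups gave as many as 2631 and 3085. The growth state of the cultures may contribute. On the first within-group component 27 of 28 mitotic genes loaded toward control replicate 2 and inhibitor replicate 3, and the list's mean loading lay at percentile 0. Growth state is not singled out, since NF-kB and immediate early genes also lay at percentile 0 and epithelial genes at 99.9. For array brightness, the correlation with the first component did not decide (Pearson r 0.276, two-sided exact permutation p 0.575, and r 0.131 without the 2 farthest arrays). Spearman rho was 0.371 (exact permutation p 0.497). The 2 arrays differed by 17.9 in mean signal against a median of 17.7 over pairs. Arrays of nearly equal mean signal lay apart. Inhibitor replicates 1 and 3 (258.5 and 257.8) lay at 17.5 and −9.11. Control replicate 2 and inhibitor replicate 2 (239.9 and 240.3) lay at −15.7 and 13.2. For these arrays, that argues against mean signal alone setting the position. Of 10 splits, 3 gave as many probes, the real one included, up to 3085 for control replicates 1 and 2 with inhibitor replicate 3 against the rest, and all 10 gave 0 past the threshold, too few splits for a share under 0.05. Exchanged labels of control replicate 3 and inhibitor replicate 3 stay open, with a camera p of 0.504 for the miR-30 targets after the exchange and 0.0252 before it, a camera p of 0.00849 against 6.78e-07 for the integrated stress response, and 5 lists past the threshold against 1.

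Lower LAMB1 and COL4A2 prompted a list of 30 other basement membrane genes, of which 17 were measured, 12 lower and 5 higher. Their camera p was 0.00369 (adjusted over the 2 later lists 0.00739), 0.0353 with an estimated correlation (adjusted p 0.0706, past no threshold), and 0.00883 without FN1, which a fixed list also held. Over 15 other alternatives the adjusted p ran from 0.00189 to 0.0877 and missed the threshold in 3, at 0.0508 without a detection filter, 0.0787 without inhibitor replicate 3 and 0.0877 without control replicate 2 and inhibitor replicate 3. Adjusted over the list alone, AGRN (−0.39), COL4A1 (−0.34) and LAMB2 (−0.22) fell and P3H2 (0.22) rose. A joint shift of basement membrane genes is consistent with these values, as a hypothesis found and tested on the same arrays whose call is lost in these 3 and with an estimated correlation, and no other explanation was tested.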
